A study of Rattus norvegicus with 24 samples.

How the data were processed

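Total RNA from the microdissected dentate gyrus of single male Long-Evans rats was hybridized to Affymetrix rat expression arrays, with tissue collected 2 weeks after behavioural testing. The deposited values are log2 probe set summaries that the authors made with GCRMA, per the submitters' processing notes, which give no version. The values, from 0.548 to 15 over the arrays used, have nearly the same quartiles on each array and are not centred per gene. Groups follow the labels: a learning index from the Morris water maze separated aged rats that performed within the young range (unimpaired) from those that performed worse (impaired). Of 24 labelled arrays, 3, 1 per group, were omitted by the submitters for quality control and their columns are empty, which leaves 21. The labels give no hybridization date or batch, so none was modelled. Young replicate 9 is listed among the unimpaired arrays but is young by its title and age, and was kept so. In a check added afterwards, each array was placed by the probe sets called for age without it. Young replicate 9 was nearer the young mean in 87.9% of 91 probe sets. The range was 43.5% to 87.9% for young arrays, this one included, and 10.5% to 36.6% for aged arrays.

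The table holds 31099 probe sets, of which 57 are controls. Probe sets other than controls were kept for testing when their log2 value was above 4 on at least 6 arrays, the size of the smallest group, which left 15177. Gene symbols came from the platform annotation: 11476 of the tested probe sets have 1 symbol, 281 have several and 3420 have none, and over all non-control probe sets the counts are 20826, 436 and 9780. Of the probe sets with 1 symbol, 20764 matched a RefSeq gene of the GRCr8 assembly by gene identifier and 0 symbols changed. No coordinates are given.

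Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with the 3 groups in 1 fit and 18 residual degrees of freedom. The contrasts were impaired minus young, unimpaired minus young, impaired minus unimpaired, and the mean of the aged groups minus young. P values were adjusted by Benjamini and Hochberg over the probe sets tested, and a probe set passed at an adjusted p below 0.05. Values are log2 differences ± the moderated standard error unless SD is stated. Where the text says that a gene lay in 7 of 7 arrays, each array of the first group was on that side of the mean of the reference group.

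Genes were named by a rule: the 10 largest positive and the 10 largest negative differences per contrast among probe sets that passed and had 1 symbol, with 1 probe set per gene, the passing one with the highest mean. A gene's printed value is therefore not always its largest: other passing probe sets gave -0.61 for Tfrc and -0.69 for D430041D05Rikl in impaired rats and 0.55 for Cdh13 in unimpaired rats. Added to these were the 5 smallest p values in a direction where fewer than 5 passed, and up to 4 members with the smallest p of each gene list that passed or had a member that passed. The individual values of Vim on single arrays, the genes shared by both comparisons with young rats and the single marker genes named for the meninges and choroid plexus were chosen after their values were seen. For 8737 genes the probe set with the highest mean represented the gene. The 32 gene lists written from textbook knowledge were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists with at least 5 measured genes. Camera compares a list with the other genes. Counts of positive or negative members and list medians are not relative to other genes. Over all tested probe sets the median log2 difference was 0.01 in impaired minus young and -0.04 in unimpaired minus young. It was 0.05 in impaired minus unimpaired and -0.01 in all aged minus young. Each list was also tested with a correlation estimated from the arrays and with fry, which asks whether the list's genes move on balance in 1 direction. A further test was a two-sided exact permutation of the arrays between groups on the list mean minus the mean of the other genes. In all contrasts the median, the mean and the test of each list that passed had the same sign. These lists, the contrasts, the filter and the naming rule were chosen before the data were examined, while the permutation of arrays for lists was added afterwards.

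Array medians, the 3' minus 5' signal of the rat Gapdh and beta-actin controls and the first principal component were compared between groups by two-sided exact permutation tests, adjusted over 9 tests. The first component held 11.9% of the variance and the second 10.6%. Scores on the first averaged -7.60 in young, 8.44 in unimpaired and 1.46 in impaired arrays. Each pair of groups differed in them (exact permutation adjusted p of 0.003 to 0.0184). Because both comparisons with young rats use the same young arrays, their correlation was set against 20 simulations without change and against 70 divisions of the young arrays into 4 and 4.

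The steps were tested on simulated data with 15177 probe sets. A log2 change of 0.5 was recovered for 89% of changed probe sets in impaired minus young, 87% in unimpaired minus young, 87% in impaired minus unimpaired and 92% in all aged minus young, with 15, 8, 24 and 12 unchanged probe sets called. In all aged minus young this was a change of 1 in the impaired group alone. Probe sets were drawn independently and many were changed, which eases the threshold. These shares therefore do not give the power of the real comparisons. A shift of 0.3 placed on 25 genes in the impaired group was recovered by camera, with 0 other lists called. Genes were drawn independently there, while genes of a list can vary together in the real arrays. The simulation therefore does not show how often camera passes a list wrongly here.

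Alternatives fixed at the outset were no filter, a filter above 6, quantile normalization, the replicate number as a block, array weights, a trended robust variance, the 3' minus 5' signal as a covariate, only the groups compared, 1 probe set or the mean of probe sets per gene, and leaving out each array. Alternatives chosen after seeing the data were median centring, the first component of the residuals as a covariate, and leaving out the 3 arrays with Ttr above 9, the 2 arrays at the ends of the first component, or the 4 arrays whose meningeal list mean was above -1.7. Every set of 3 impaired arrays and 1 young array was also left out, 280 sets in all, as a comparison with the last of these. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Individual maze scores are not given in the sources used here, so no gene was related to learning within a group.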

Results

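Transcript levels in the dentate gyrus, the hippocampal field in which neurons are still born in adult rats, were compared between young and aged male Long-Evans rats. Aged rats were divided by their spatial learning in the Morris water maze, a swimming task in which the animal searches for a hidden platform. The 21 arrays came from 8 young rats aged 6 months, 6 aged rats with unimpaired learning and 7 aged rats with impaired learning. Aged rats were 24 to 26 months old, and each array is labelled as a separate animal. Array medians lay between 3.77 and 3.84 on the log2 scale, and 48.3% to 48.8% of probe sets on each array were above a log2 level of 4. Each array correlated with the others of its group at an r of 0.989 to 0.992 across probe sets. The 3' minus 5' signal of the control transcripts, a measure of RNA integrity, averaged 1.43 ± 0.05 (SD) in young, 1.40 ± 0.04 in aged unimpaired and 1.42 ± 0.06 in aged impaired rats. No pair of groups differed in a two-sided exact permutation test (adjusted p of 0.441 to 0.759). For arrays, the number of animals limits the precision of every value below.

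The comparison of all aged rats with young rats asks how the mean of the aged groups differs from young rats. A large difference in 1 aged group can carry such a call, so a call does not show a change in both. Sema3c, which encodes a secreted semaphorin that guides growing axons, fell by 1.68 ± 0.16 (SE) on the log2 scale, a level 3.20 times lower (adjusted p = 4.74e-06). Each of the 13 aged arrays lay below each of the 8 young arrays. Glra2, a glycine receptor subunit, fell by 1.90 ± 0.24 (adjusted p = 0.000246) and was below the young mean in 13 of 13 aged arrays. Slco1c1, a thyroid hormone transporter of brain vessels, fell by 0.53 ± 0.06 (adjusted p = 3.16e-05) in 13 of 13 arrays. Ptpro, a receptor tyrosine phosphatase, fell from a mean of 7.57 in young to 6.48 in unimpaired and 6.66 in impaired rats (adjusted p = 0.0121), also in 13 of 13 arrays. Pcdhb17, a clustered protocadherin, rose by 1.29 ± 0.10 (adjusted p = 7.25e-07) and Nat8f3 by 1.31 ± 0.19 (adjusted p = 0.00117), both above the young mean in 13 of 13 arrays. Pcdhb17 averaged 3.88 ± 0.22 (SD) in young rats, below the level of 4 used as a filter, and related protocadherin and Nat8f genes can share probe targets.

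Other genes that rose with age, each in 13 of 13 arrays, were Ccn2, a matricellular growth factor, by 1.52 ± 0.33 (adjusted p = 0.0256), and Cd302 by 0.70 ± 0.11 (adjusted p = 0.00227). The complement component C3 rose by 1.20 ± 0.28 (adjusted p = 0.0359), also in 13 of 13 arrays. Bmp6, a bone morphogenetic protein, rose by 0.63 ± 0.10, the kynurenine pathway enzyme Aadat by 0.72 ± 0.13 and the lysosomal protease Ctsz by 0.67 ± 0.13. The glutathione transferase Mgst1 rose by 0.74 ± 0.18 and the alkaline ceramidase Acer2 by 1.45 ± 0.34. The remaining genes with large falls, each in 13 of 13 arrays, were L3mbtl3 at -0.91 ± 0.20, Ugt8 at -0.78 ± 0.17 and Col4a5 at -0.69 ± 0.15. Alike in direction and number of arrays were Nid1 at -0.65 ± 0.14, Fstl5 at -0.61 ± 0.12 and Qpct at -0.52 ± 0.11. Col4a5 and Nid1 encode proteins of the basement membrane, and Ugt8 makes a lipid of myelin.

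Markers of neural progenitors and immature neurons were lower in aged rats. Of 26 listed markers on the array, 11 passed the filter on level and were measured. Of these 11, 10 had a negative difference, 2 fell over all probe sets and 5 when adjusted over the list alone. Nrep fell by 0.42 ± 0.07 (adjusted p = 0.00389) and Sox4 by 0.52 ± 0.10 (adjusted p = 0.0124), both in 13 of 13 arrays. The list lay below other genes by a log2 difference of -0.19 (camera adjusted p = 2.15e-05). It had an adjusted p = 0.154 with an estimated correlation and an adjusted p = 0.00171 when the arrays were permuted between groups. Lysosomal genes were higher: 19 of 25 had a positive difference, and Ctsz and Npc2 rose, the latter by 0.32 ± 0.07 (adjusted p = 0.0177). In that list 5 rose when adjusted over the list alone. The camera adjusted p was 2.15e-05, with an adjusted p = 0.251 with an estimated correlation and a permutation adjusted p of 0.00962.

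Microglia and macrophage markers, of which 12 of 26 on the array were measured, were also higher. Of the 12, 11 were positive, 1 rose over all probe sets and 4 rose when adjusted over the list alone. Fcer1g, a signalling chain of Fc receptors, was the 1 that rose, by 0.38 ± 0.09 (adjusted p = 0.035). The list had a camera adjusted p of 2.15e-05, an adjusted p = 0.244 with an estimated correlation and a permutation adjusted p of 0.0585. Of 7 complement genes, 6 were positive and C3 and C1qa rose, C1qa by 0.45 ± 0.10 (adjusted p = 0.028), or 3 genes when adjusted over the list alone. The camera adjusted p was 0.00136, with an adjusted p = 0.225 with an estimated correlation and a permutation adjusted p of 0.033. Markers of oligodendrocyte precursors were negative in 6 of 6 cases, 0 by limma over all probe sets and 5 when adjusted over the list alone. The list had a camera adjusted p of 0.00136, an adjusted p = 0.225 with an estimated correlation and a permutation adjusted p of 0.0444. Of 22 oligodendrocyte and myelin genes, 16 were negative. Mal (-0.48 ± 0.09) and Cldn11 (-0.43 ± 0.09), each below the young mean in 12 of 13 arrays, fell together with Tspan2 and Ugt8, while Qdpr, an enzyme of biopterin metabolism, rose. Adjusted over the list alone 1 rose and 5 fell, and the camera adjusted p was 0.0259, with an adjusted p = 0.734 with an estimated correlation and a permutation adjusted p of 0.213. Further lists had a camera adjusted p below 0.05 that was lost with an estimated correlation and when the arrays were permuted. Oxidative phosphorylation genes were negative in 41 of 46 cases (adjusted p = 0.0238; adjusted p = 0.824 with an estimated correlation), 0 of them past limma's threshold when adjusted over the list alone. Heat shock proteins and chaperones were negative in 21 of 28 cases (adjusted p = 0.0259; adjusted p = 0.734 with an estimated correlation), and 2 fell when adjusted over the list alone. Interferon response genes, of which 5 of 23 on the array were measured, were positive in 5 of 5 cases. Their camera adjusted p was 0.026, or 0.225 with an estimated correlation, and 0 passed in limma when adjusted over the list alone. Glucocorticoid-responsive genes were positive in 8 of 11 cases (adjusted p = 0.0303; adjusted p = 0.625 with an estimated correlation), and 3 rose and 1 fell when adjusted over the list alone. Oxidative stress genes were positive in 13 of 23 cases (adjusted p = 0.0461; adjusted p = 0.625 with an estimated correlation), and 2 rose when adjusted over the list alone. The oxidative stress call was kept in 9 of 21 fits with 1 array left out and in 6 of 10 other alternatives, not with median centring or without the arrays with high meningeal markers. The glucocorticoid call was kept in 17 of 21 and 5 of 10. The interferon and oxidative phosphorylation calls were lost with median centring and quantile normalization, and the heat shock call with a filter above 6 and with array weights. Permutation adjusted p values were 0.413 for oxidative phosphorylation, 0.376 for heat shock, 0.155 for interferon and glucocorticoid and 0.116 for oxidative stress genes. Over all probe sets limma called 1 gene of the oxidative stress list and 0 of the other 4. The astrocyte filament gene Gfap rose by 0.40 ± 0.08 (adjusted p = 0.0154) and the opioid precursor gene Pdyn by 0.36 ± 0.07 (adjusted p = 0.0138), each in 13 of 13 arrays. The glutathione transferase Gstp1 rose by 0.33 ± 0.04 (adjusted p = 0.000246), also in 13 of 13 arrays.

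Among 15177 probe sets, limma called 168 for age, 61 higher and 107 lower. They held 123 genes with a single symbol, and 8 of the probe sets differed at least 2-fold. The balance of directions depended on scaling, with 116 higher and 87 lower after median centring and 124 higher and 108 lower after quantile normalization. Without the 4 arrays with high meningeal markers described for the impaired rats, 86 probe sets were called. Leaving out a random array from each group, in 100 draws, left a median of 80.5 (45 to 227). Those draws do not match the 4 arrays in number or group. The lower count therefore does not single out meningeal tissue from the loss of arrays.

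Impaired aged rats were compared with young rats to describe age in animals that learned poorly. Sema3c fell by 1.88 ± 0.18, a level 3.69 times lower (adjusted p = 7.31e-06). It averaged 8.17 ± 0.32 (SD, n = 8) in young and 6.29 ± 0.47 (n = 7) in impaired rats. Slc7a1, a transporter of cationic amino acids, fell by 0.60 ± 0.07 (adjusted p = 0.000154), and Slco1c1 by 0.55 ± 0.06 (adjusted p = 0.000146). Tubb2b, a tubulin of developing neurons, fell by 0.51 ± 0.07 (adjusted p = 0.00069) and the transferrin receptor gene Tfrc by 0.46 ± 0.07 (adjusted p = 0.00272), each in 7 of 7 arrays. Pcdhb17 rose by 1.48 ± 0.12 (adjusted p = 8.33e-07), and Bmp6 by 0.74 ± 0.12 (adjusted p = 0.00472). Nat8f3 rose by 1.49 ± 0.22 and the macrophage gene Mpeg1 by 0.64 ± 0.09, both with an adjusted p of 0.00176, and all of these in 7 of 7 arrays.

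Further genes that rose were Ccn2 at 1.90 ± 0.38, Gpnmb at 0.81 ± 0.18, Ctsz at 0.77 ± 0.15, Cd302 at 0.75 ± 0.13, Aadat at 0.71 ± 0.15 and Tspo, a mitochondrial outer membrane protein, at 0.61 ± 0.11. Genes that fell included Glra2 at -1.61 ± 0.28, Col4a5 at -0.84 ± 0.18, the transcription factor gene Sox4 at -0.56 ± 0.11, D430041D05Rikl at -0.49 ± 0.09 and Ddah1 at -0.50 ± 0.10. Ddah1 lay below the young mean in 6 of 7 arrays and the others in 7 of 7. Of the 20 genes named for the size of their difference, 10 passed under each of up to 34 settings: Bmp6, Cd302, Mpeg1, Nat8f3, Pcdhb17, Sema3c, Slc7a1, Slco1c1, Tfrc and Tubb2b.

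Lysosomal genes were higher in impaired than in young rats in 23 of 25 cases. Ctsz, the lysosomal glucosidase Gaa (0.23 ± 0.05) and the cholesterol carrier Npc2 (0.34 ± 0.08) rose over all probe sets, and 9 genes rose when adjusted over the list alone. The list had a camera adjusted p of 1.38e-05, an adjusted p = 0.337 with an estimated correlation and an exact permutation adjusted p of 0.0338. All 12 measured microglia and macrophage markers were positive. Over all probe sets limma called 0, and 6 rose when adjusted over the list alone, as with Ctss (0.31 ± 0.08) and Fcer1g (0.41 ± 0.10). The camera adjusted p was 3.9e-05, and the list had an adjusted p = 0.337 with an estimated correlation and an exact permutation adjusted p of 0.173. Progenitor and immature neuron markers were negative in 10 of 11 cases, Sox4 and Nrep (-0.36 ± 0.08) fell, and 5 fell when adjusted over the list alone. That list had a camera adjusted p of 0.000275, an adjusted p = 0.337 with an estimated correlation and an exact permutation adjusted p of 0.0338.

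Heat shock proteins and chaperones were negative in 19 of 28 cases, and 2 fell when adjusted over the list alone (camera adjusted p = 0.00524; adjusted p = 0.597 with an estimated correlation). Dnajc3 and Hspa5, chaperones of the endoplasmic reticulum, had differences of -0.49 ± 0.12 and -0.31 ± 0.09. Oxidative phosphorylation genes were negative in 33 of 46 cases with a median log2 difference of only -0.02 (camera adjusted p = 0.0436; adjusted p = 0.847 with an estimated correlation). Complement genes were positive in 5 of 7 cases, with C3 at 0.97 ± 0.32 and 3 that rose when adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.56 with an estimated correlation). This call was kept in 11 of 21 fits with 1 array left out, with an adjusted p of 0.163 without impaired replicate 2, and was lost without the arrays with high meningeal markers, high transthyretin (Ttr) or extreme component scores. The oxidative phosphorylation call was kept in 15 of the 21. Exact permutation adjusted p values were 0.197 for heat shock, 0.212 for oxidative phosphorylation and 0.173 for complement genes. Gfap (0.43 ± 0.09), Qdpr (0.42 ± 0.09), Pdyn (0.36 ± 0.08) and Gstp1 (0.40 ± 0.05) also rose in 7 of 7 arrays.

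Markers of the meninges, the membranes that cover the brain, were uneven among the impaired rats. The mean of the meningeal list relative to other genes was -0.77, -0.72 and -1.27 on impaired replicates 2, 3 and 7 and -1.61 on young replicate 5, against -2.91 to -1.87 on the other 17 arrays. Vim, an intermediate filament of fibroblasts and astrocytes, reached 9.99, 9.71 and 9.01 on those impaired arrays and averaged 7.93 ± 0.22 in young rats. The list did not pass against young rats (median 0.29, camera adjusted p = 0.139). Without the 4 arrays the difference of Ccn2 was 1.53 ± 0.29 (adjusted p = 0.0404). The lysosomal genes Ctsz, Gaa and Npc2 had differences of 0.73 ± 0.17, 0.20 ± 0.06 and 0.28 ± 0.08, each within 1 SE of the value with all arrays, and did not pass (adjusted p of 0.148, 0.25 and 0.235). Leaving out any 3 impaired arrays and 1 young array ended these 3 calls in 252, 235 and 249 of 280 sets and that of Ccn2 in 229.

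For impaired against young rats limma called 78 probe sets, 47 higher and 31 lower, holding 58 single-symbol genes, and 6 differed at least 2-fold. The count was 29 without the 4 arrays with high meningeal markers, and 216 of the 280 sets of 3 impaired arrays and 1 young array left as few, with a median of 16. It ranged from 36 without impaired replicate 2 to 161 without young replicate 5 when arrays were left out in turn.

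**Figure D1:**
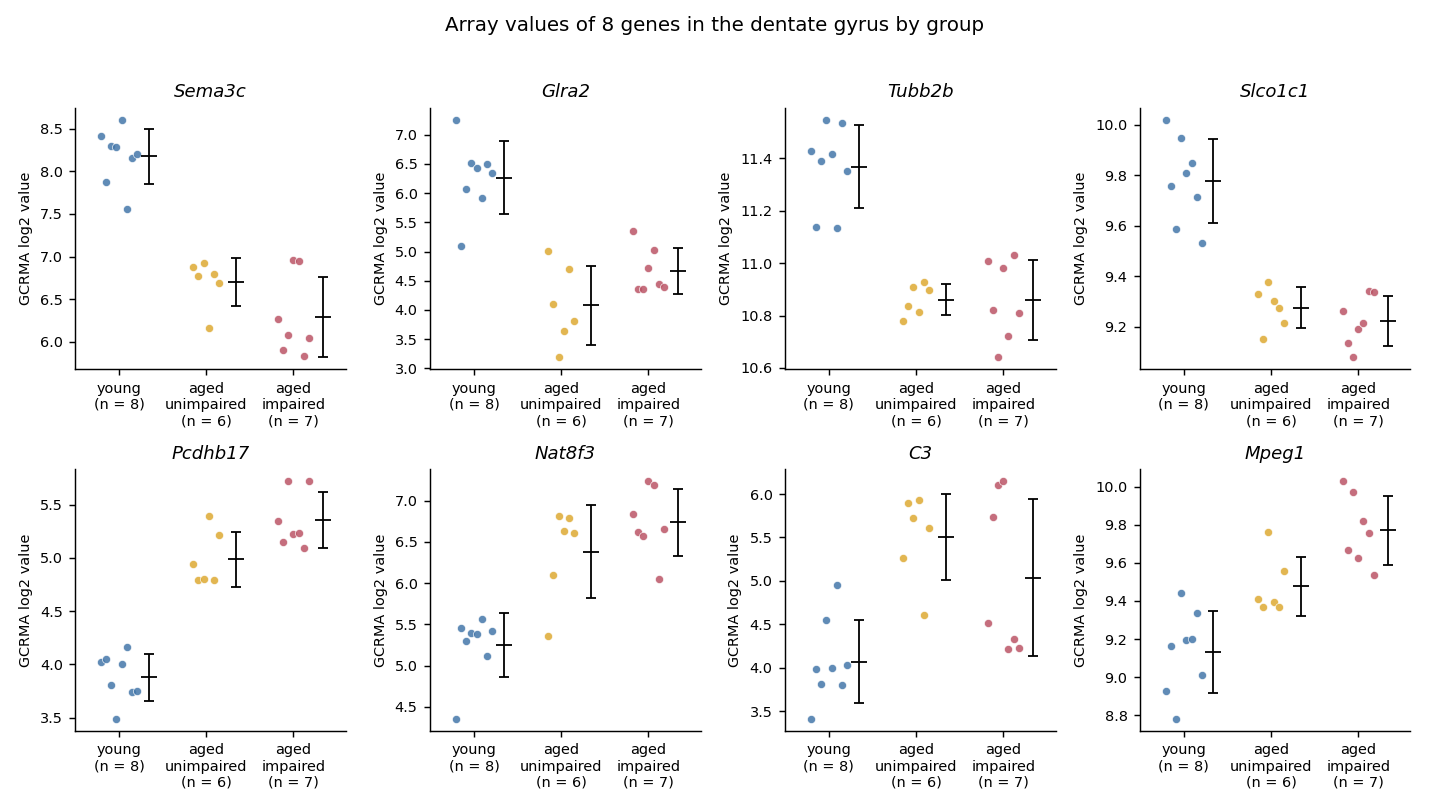
Expression of 8 genes in log2 units (vertical axis) in young, aged unimpaired and aged impaired rats (horizontal axis), with 1 point per array and bars for the mean and SD. Sema3c averaged 8.17 in young, 6.70 in unimpaired and 6.29 in impaired rats, and Pcdhb17 averaged 3.88, 4.99 and 5.35.

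Unimpaired aged rats were compared with young rats to describe age in animals whose learning stayed within the range of the young. Glra2 fell by 2.19 ± 0.29 (adjusted p = 0.000691) and Sema3c by 1.47 ± 0.19 (adjusted p = 0.000607), each in 6 of 6 arrays. Glra2 was below the filter level of 4 in 3 of the 6, so the size of its fall is uncertain. Some genes of myelin fell as well. Cldn11, a tight junction protein of the myelin sheath, fell by 0.64 ± 0.10 (adjusted p = 0.00622), and Mal by 0.63 ± 0.11 (adjusted p = 0.0121). Ugt8 fell by 0.91 ± 0.21 (adjusted p = 0.0355), and all 3 were lower in 6 of 6 arrays. Mbp and Mobp, the most abundant genes of the myelin list, differed by only -0.03 and -0.04. Pcdhb17 rose by 1.11 ± 0.13 (adjusted p = 0.000261), C3 by 1.44 ± 0.33 (adjusted p = 0.0381) and the complement recognition gene C1qa by 0.49 ± 0.12 (adjusted p = 0.0463), also in 6 of 6 arrays.

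Nat8f3 rose by 1.14 ± 0.23, Aadat by 0.72 ± 0.15, Cd302 by 0.65 ± 0.13, and Bmp6 by 0.52 ± 0.12. Cdh13, a cadherin, rose by 0.41 ± 0.08, Plag1 by 0.40 ± 0.09 and Smarcc2 by 0.49 ± 0.11, the last above the young mean in 5 of 6 arrays. Ptpro fell by 1.09 ± 0.23, Nid1 by 0.82 ± 0.17, Qpct by 0.68 ± 0.13, Fstl5 by 0.64 ± 0.14 and Sox17, a transcription factor of endothelial cells, by 0.63 ± 0.11, each in 6 of 6 arrays. Of the 20 genes named for size, 5 passed under each of up to 34 settings, namely Cldn11, Glra2, Pcdhb17, Qpct and Sema3c.

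All 11 measured progenitor and immature neuron markers were negative in unimpaired rats, where the median over all tested probe sets was -0.04. Nrep (-0.47 ± 0.08, adjusted p = 0.0121) and Tubb3 (-0.19 ± 0.05, adjusted p = 0.0466) fell over all probe sets and 7 fell when adjusted over the list alone. The list had a camera adjusted p of 0.000318, an adjusted p = 0.195 with an estimated correlation and an exact permutation adjusted p of 0.0483. All 6 oligodendrocyte precursor markers were negative as well. Vcan (-0.60 ± 0.13) and the growth factor receptor gene Pdgfra (-0.34 ± 0.07) fell, or 4 genes when adjusted over the list alone (camera adjusted p = 0.000832; adjusted p = 0.195 with an estimated correlation). Of 22 oligodendrocyte and myelin genes 19 were negative, Cldn11, Mal, Tspan2 (-0.45 ± 0.08) and Ugt8 fell, and when adjusted over the list alone 10 fell and 2 rose. That list had a camera adjusted p of 0.00137, an adjusted p = 0.631 with an estimated correlation and an exact permutation adjusted p of 0.0579, and without unimpaired replicate 1 its camera adjusted p was 0.0679.

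Complement genes were positive in 6 of 7 cases, with C3 and C1qa rising and 2 that rose when adjusted over the list alone (camera adjusted p = 0.000832; adjusted p = 0.195 with an estimated correlation). Microglia and macrophage markers were positive in 9 of 12 cases, 0 by limma over all probe sets and 1 when adjusted over the list alone (camera adjusted p = 0.000921; adjusted p = 0.551 with an estimated correlation). Lysosomal genes were positive in 17 of 25 cases with a median of 0.03, 0 by limma over all probe sets and 2 when adjusted over the list alone. That list had a camera adjusted p of 0.000921 and an adjusted p = 0.61 with an estimated correlation. Endothelial and pericyte markers were negative in 11 of 14 cases. Slco1c1 (-0.50 ± 0.07), the angiopoietin receptor gene Tek (-0.51 ± 0.09) and the transporter gene Slco1a4 (-0.40 ± 0.10) fell, or 4 genes when adjusted over the list alone (camera adjusted p = 0.0466; adjusted p = 0.648 with an estimated correlation). Glucocorticoid-responsive genes were positive in 8 of 11 cases, with Fkbp5 at 0.30 ± 0.08 and 1 that rose when adjusted over the list alone (camera adjusted p = 0.0428; adjusted p = 0.631 with an estimated correlation). The endothelial call was kept in 13 of 21 fits with 1 array left out and in 6 of 10 other alternatives, not with the replicate number as a block (adjusted p = 0.0553) or without the arrays with high meningeal markers. The glucocorticoid call was kept in 15 of 21 and 5 of 10, not with no filter, quantile normalization or median centring. With the arrays permuted between groups, the oligodendrocyte precursor, complement and lysosomal lists did not pass (exact permutation adjusted p = 0.0531 for each), nor did the microglia (0.296), endothelial (0.159) and glucocorticoid lists (0.284). The proteasome gene Psmc6 fell by 0.21 ± 0.05, while its list did not pass (camera adjusted p = 0.357).

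For unimpaired against young rats limma called 172 probe sets, 30 higher and 142 lower, holding 127 single-symbol genes, and 6 differed at least 2-fold. This direction depended on scaling, since median centring gave 62 higher and 53 lower and quantile normalization 64 higher and 61 lower. Unimpaired arrays had a lower median over the tested probe sets (7.76 ± 0.04, SD) than young (7.81 ± 0.04) and impaired arrays (7.82 ± 0.02). The exact permutation p values were 0.037 and 0.00233, or 0.0665 and 0.00839 after adjustment over 9 array tests. The count was 17 without young replicate 9 and unimpaired replicate 4, the arrays at the ends of the first principal component. It was 95 without the 4 arrays with high meningeal markers, of which only young replicate 5 belongs to a group compared here. Leaving out a random array from each group, in 100 draws, left a median of 54 (13 to 215). The count of 95 therefore does not single out meningeal tissue from the loss of arrays.

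**Figure D2:**
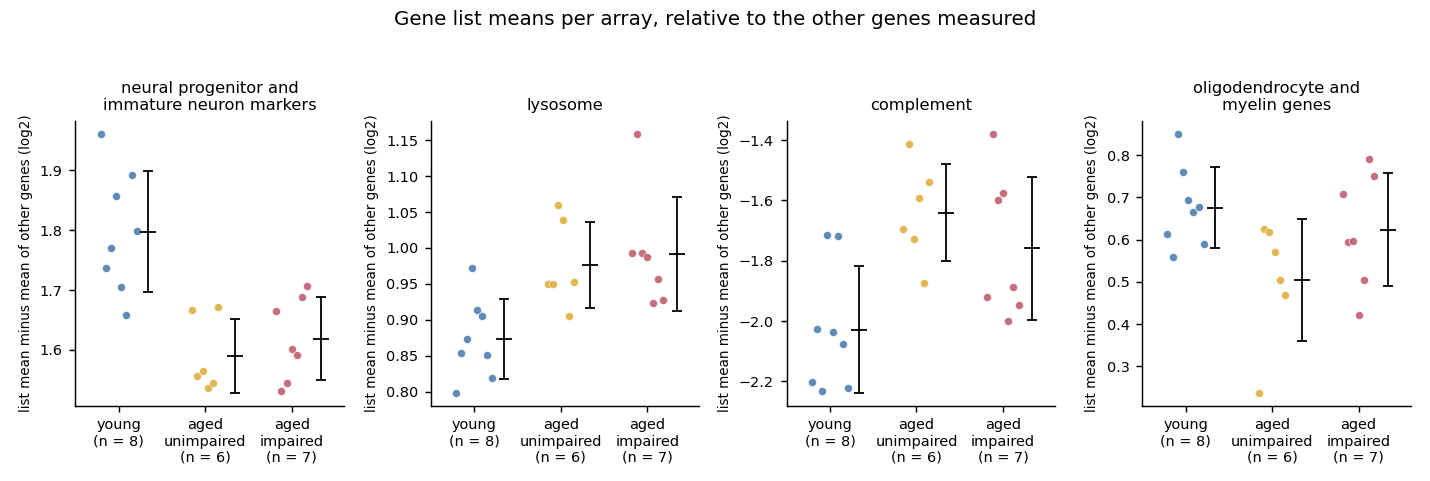
Mean log2 level of 4 gene lists minus the mean of the other genes (vertical axis) in young, aged unimpaired and aged impaired rats (horizontal axis), with 1 point per array and bars for the mean and SD. Progenitor and immature neuron markers lay lower in both aged groups than in young rats, by -0.21 in unimpaired and -0.18 in impaired rats.

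The genes called against young rats overlapped between the aged groups. Of 220 probe sets called in either comparison, 30 were called in both, 11 higher and 19 lower, and 0 by limma in opposite directions. Independent lists would share 0.0929 higher and 0.29 lower probe sets, but the shared young arrays raise the overlap by themselves. Simulated data without change shared 0. Almost no probe set can pass there in either comparison, so this value says nothing about the overlap. The shared genes included Sema3c, Glra2, Slco1c1, Tfrc, Tubb2b and Nrep among those that fell, with Sox4 by a probe set other than the one given above, and Pcdhb17, Nat8f3, Cd302, Bmp6, Aadat, Pdyn and Gstp1 among those that rose. Across probe sets, which are not independent replicates, the differences of the aged groups from young rats correlated at an r of 0.574. The r was 0.449 in simulated unchanged data that share the young arrays and had a median of 0.276 when the young arrays were divided into 4 and 4 so that none was shared. The covariance of the differences was 0.012 observed and 0.0051 simulated, while the share with the same sign was no higher than in simulated data (64.5% observed, 64.7% simulated). The share decides little, because the real differences had medians of opposite sign (0.01 in impaired and -0.04 in unimpaired rats). Such shifts lower the share by themselves, and the simulated data had none built in.

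Impaired and unimpaired aged rats were compared to find differences that go with learning at the same age, and no gene passed. The genes with the smallest p values were higher in impaired rats for the adenylate cyclase gene Adcy5 (0.36 ± 0.07), Leprot (0.29 ± 0.06), Pir (0.41 ± 0.08), Armc9 (0.38 ± 0.08) and Lsm5 (0.34 ± 0.07). They were lower for LOC102549828 (-0.81 ± 0.18), the transcription factor gene Mycl (-0.51 ± 0.12), Slc7a1 (-0.34 ± 0.08), Phc3 (-0.26 ± 0.06) and Ap3b1 (-0.34 ± 0.08). Each lay beyond the unimpaired mean in 7 of 7 impaired arrays with an adjusted p of 0.129. Slc7a1 averaged 7.82 ± 0.16 (SD) in young, 7.57 ± 0.11 in unimpaired and 7.23 ± 0.14 in impaired rats. Sema3c and Pcdhb17, which differed most firmly from young rats in both aged groups, were not among the genes with the smallest p values here.

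Oligodendrocyte and myelin genes were positive in 20 of 22 cases in impaired relative to unimpaired rats, with Cldn11 at 0.42 ± 0.11, Mag at 0.39 ± 0.11, Opalin at 0.47 ± 0.15 and Evi2a at 0.26 ± 0.08. Over all probe sets 0 passed in limma, 7 rose when adjusted over the list alone, and the median was 0.20. The median over all tested probe sets was 0.05 in this contrast, so part of the sign count goes with a general difference. The list had a camera adjusted p of 0.0219, an adjusted p = 0.989 with an estimated correlation and an exact permutation adjusted p of 0.577. Relative to other genes the list differed by 0.12 ± 0.07 with all arrays and by 0.09 ± 0.08 without the 4 arrays with high meningeal markers. It did not pass without them (adjusted p = 0.221), nor in 113 of the 280 sets in all, nor without unimpaired replicate 1 (adjusted p = 0.269) or with a filter above 6. The other 28 lists had camera adjusted p values of 0.105 to 0.988, the lowest for GABAergic interneuron markers (10 of 10 positive, median 0.17) and endothelial and pericyte markers (12 of 14 positive, median 0.23), both at 0.105. Some of these lists passed under an alternative. The lowest camera adjusted p was 0.00343 for the endothelial and oxidative phosphorylation lists and 0.0102 for the GABAergic list. It was 0.0151 for oligodendrocyte precursor and 0.0291 for meningeal markers. The highest adjusted p over the alternatives was 0.989 for each of them.

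Limma called 0 probe sets between the aged groups at a smallest adjusted p of 0.129, while 2199 had an unadjusted p below 0.05, 1949 of them higher in impaired rats, against 758.9 expected by chance. Of the list tests, the estimated correlation, fry and the permutation of arrays each called 0. After median centring 41.9% of the 1588 probe sets at that level were higher, against 88.6% before it. The aged groups differed on the first principal component (means of 1.46 in impaired and 8.44 in unimpaired arrays, exact permutation adjusted p = 0.0184). The arrays were not median centred for it. Their medians over the tested probe sets also differed between the aged groups (7.82 and 7.76, exact permutation adjusted p = 0.00839). The arrays at its ends, young replicate 9 and unimpaired replicate 4, had the highest and the lowest median (7.88 and 7.70). This difference cannot be told apart from one in array level.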

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

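The tests of RNA integrity, choroid plexus tissue, centring of the myelin list and oligodendrocyte share were chosen only after the result was seen, as were the sets of arrays left out for comparison and the arrays with high Ttr, high meningeal markers or extreme component scores; the rule for oligodendrocyte share was changed after a first version had been run.

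The meningeal list was high on impaired replicates 2, 3 and 7 (-0.77, -0.72 and -1.27) and on young replicate 5 (-1.61), against at most -1.87 elsewhere, and a candidate explanation is meningeal tissue in the dissected sample. Of 6 other listed meningeal genes with a value above 4 on any array, 6 had their highest value on 1 of these 4 arrays, where 1.14 would be expected by chance, but each of the 6 peaked on impaired replicate 2 or 3, so for impaired replicate 7 and young replicate 5 meningeal tissue stays open. Transthyretin (Ttr), a choroid plexus transcript, exceeded log2 9 on impaired replicate 7 (10.09), unimpaired replicate 3 (9.43) and young replicate 2 (10.78) against at most 7.28 elsewhere, but 0 of 14 other choroid plexus markers were higher on all 3 arrays, and since only 2 of the 14 have any value above 4 the test leaves choroid plexus tissue open. Without the 3 arrays with high Ttr 79 probe sets were called for age, and 50% of 100 random sets of 3 arrays, 1 per group, left as few, in line with the loss of arrays alone. A response of the meninges to age or impairment was not tested and stays open.

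More probe sets were lower than higher in unimpaired rats against young rats (142 against 30). A first test of an offset between arrays by median centring fitted that explanation, as the share of lower probe sets at an unadjusted p below 0.05 moved from 81.3% to 39.4%, but centring removes such an imbalance whatever its cause, so the test was replaced after its result was seen. In the replacement, a uniform offset would shift weak and strong probe sets alike. The median difference was -0.01, -0.03, -0.05 and -0.05 in 4 equal classes of probe sets from the lowest to the highest mean level. The span was 0.0437 (SE 0.0209), and a further check on the upper classes, added afterwards, gave 0.0197 (SE 0.00646). Both spans compare the highest and the lowest class picked from these same data, and their SE does not allow for that choice. They weigh only weakly against a uniform offset. An offset that grows with level stays open, as does a broad fall of transcripts in unimpaired aged rats, which was not tested apart from these. For RNA integrity, 88.0% of calls were lower with the 3' minus 5' signal as a covariate. This decides little, because the signal was much alike in unimpaired and young arrays (1.40 and 1.43, exact permutation adjusted p = 0.441). A covariate so alike can hardly change the direction of calls. Without young replicate 9 and unimpaired replicate 4 the share of lower probe sets at an unadjusted p below 0.05 was 74.2%. It was 81.3% with all arrays, and 74.2% lies between the bounds set for that explanation.

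The oligodendrocyte and myelin list was higher in impaired than in unimpaired rats (camera adjusted p = 0.0219 by the test of the difference, 0.000149 to 0.989 over the alternatives). A uniform offset between arrays moves the list and the other genes alike, so it cannot by itself make a difference between them. Centring leaves that difference as it was, so the test by centring cannot decide. Camera's adjusted p moved all the same, from 0.0219 to 0.00115 with centring, while the exact permutation adjusted p was 0.577. An offset that varies with level stays open. The median of impaired minus unimpaired ran from 0.03 to 0.06 over the 4 classes of probe sets by mean level. A smaller share of oligodendrocytes in the unimpaired samples may contribute and cannot be told apart: members above log2 11 differed by -0.13 (bootstrap SE 0.0637) from the others, but only 2 members lie at that level. Without the 4 arrays with high meningeal markers the difference relative to other genes was 0.09 ± 0.08 (SE) against 0.12 ± 0.07 (adjusted p = 0.221), and 113 of 280 sets of 3 impaired arrays and 1 young array, this one included, ended the call, so meningeal tissue is not singled out as its source. A link to learning stays open as untested.

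Single arrays far from the others of their group were found in 9 of 153 groups of values tested, where chance alone would give 7.65. Lysosomal genes averaged 9.33 on impaired replicate 2 against 9.02 to 9.14 on the other impaired arrays. Oxidative stress genes averaged 9.57 on the same array against 9.36 to 9.44. Nat8f3 was 4.35 on young replicate 9 against 5.11 to 5.57 on the other young arrays. Aadat was 6.55 on impaired replicate 8 against 5.84 to 6.13. Sema3c was 6.16 on unimpaired replicate 6 against 6.69 to 6.92, Col4a5 on this array was 4.18 against 4.72 to 4.87, and Smarcc2 was 7.20 against 7.74 to 8.02. Young replicate 5 had a Tfrc value of 10.46 against 10.71 to 10.93 and an Acer2 value of 6.39 against 3.35 to 4.08.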

How the results depend on the processing

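The settings without high-Ttr arrays, without high-meningeal arrays, without component-end arrays, with median centring, with the residual component, and with permutation of arrays were tests chosen only after the result was seen. No named gene or list reversed direction while passing. Apart from leave-outs, the named genes kept their side of the threshold in 2421 comparisons, lost it in 197 and gained it in 66, and the lists did so in 1354, 93 and 45; with arrays left out in turn the counts were 3984, 369 and 36 for genes and 2323, 63 and 50 for lists. Impaired against young gave 33 probe sets with no filter, 24 without high-Ttr arrays, 31 without component-end arrays, 29 without high-meningeal arrays and 33 with only the groups compared, against 78. Unimpaired against young gave 67, 38, 17, 95 and 69 in the same order and 307 with the residual component, against 172. All aged against young gave 90, 79, 73 and 86 in the first 4 of these and 259 with the residual component, against 168. Impaired against unimpaired gave 1 with only the groups compared, against 0. Leaving out arrays in turn gave 36 to 161 for impaired against young: 36 without impaired replicate 2 and without young replicates 9 and 3, 37 without young replicate 6, 39 and 45 without impaired replicates 3 and 7, 41 without young replicate 7, 51 without unimpaired replicate 3 and 161 without young replicate 5. It gave 59 to 219 for unimpaired against young: 59 and 67 without young replicates 9 and 6, and 92, 110, 80, 111 and 78 without unimpaired replicates 1, 3, 4, 6 and 8. It gave 89 to 239 for all aged against young, with 91 and 89 without young replicates 9 and 6, and 0 to 4 for impaired against unimpaired, with 4 without unimpaired replicate 7. The number of lists that passed was 0 in each comparison with an estimated correlation, against 6, 8, 1 and 11 for impaired, unimpaired, impaired against unimpaired, and all aged. With permutation of arrays it was 2, 1, 0 and 4. Fry gave 3 for unimpaired, 0 for impaired against unimpaired and 2 for all aged, and a filter above 6 gave 7 for all aged. For impaired against unimpaired it was 0 with a filter above 6 and without high-meningeal arrays, 6 with quantile normalization, 5 with median centring, 2 with array weights and without high-Ttr arrays, and 4 without component-end arrays. With arrays left out in turn the lists numbered 4 to 11 for impaired (11 without impaired replicate 4), 5 to 9 for unimpaired (5 without unimpaired replicate 1) and 8 to 12 for all aged. For impaired against unimpaired they numbered 0 to 4: 0 without impaired replicates 7 or 8 and unimpaired replicates 1 or 7, 2 without impaired replicates 1 or 4 and unimpaired replicates 6 or 8, and 4 without unimpaired replicate 4. Fewer arrays, more probe sets to adjust over or fewer residual degrees of freedom can lower counts. Counts also rose, to 161 without young replicate 5 in impaired against young and to 307 with the residual component in unimpaired against young. The cause of these shifts was not tested. The replicate number as a block gave 108, 197, 0 and 219 probe sets at a consensus correlation of 0.0562; whether the numbers mark anything shared stays open. The 17 same-numbered pairs had a median residual r of -0.01 and 4 above 0.1, and the 129 other pairs a median near 0 and 12 above 0.1. Of 19 arrays 7 correlated best with their own number, against 2.51 on average when numbers were shuffled within groups (permutation p = 0.0285, added afterwards). The planned fit of all 24 arrays was not run because the 3 omitted arrays have no values, and only the groups compared gives no separate fit for all aged rats. Probe sets near a log2 level of 4 lie close to background, which limits what can be said of the size of the differences of Pcdhb17, Qpct, C3, Glra2, Acer2 and L3mbtl3.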

Other observations

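The random splits were planned; the values of lists below were described after they were seen. Markers of dentate granule neurons did not move in 1 direction as a list, with median differences of 0.01 in impaired and 0.00 in unimpaired rats against young (camera adjusted p = 0.819 and 0.303). Members differed both ways: adjusted over the list alone, 2 rose in impaired rats, 2 rose and 2 fell in unimpaired rats, and 3 rose and 3 fell in all aged rats, none of which passed in limma over all probe sets. Markers of CA1 and CA3 pyramidal neurons, from neighbouring fields, were negative in 10 of 11 cases in both (medians -0.11 and -0.21, adjusted p = 0.0947 and 0.18). GABAergic interneuron markers had medians of 0.13 and -0.09 (adjusted p = 0.118 and 0.761), and astrocyte markers 0.01 and -0.02 (adjusted p = 0.804 and 0.829). Synaptic lists did not pass in any contrast, with medians in impaired and unimpaired rats of -0.01 and -0.09 for glutamate receptors, 0.00 and -0.03 for GABA receptors and 0.03 and -0.05 for presynaptic release genes. Ion channels (0.04 and -0.01), neuropeptides and trophic factors (0.10 and -0.09), immediate early genes (0.01 and -0.14), circadian clock genes (0.07 and -0.01), antigen presentation genes (0.15 and 0.03) and extracellular matrix genes (0.05 and -0.07) did not pass either. Nor did ribosomal proteins (0.02 and -0.02), proteasome (0.01 and -0.04) and cholesterol synthesis genes (0.00 and -0.04). The signs of median, mean and test differed in several of these, such as granule neuron markers in impaired rats (median and mean positive, test negative). Mossy cell, choroid plexus and red blood cell lists had 2, 2 and 1 measured genes and could not be tested. The list medians given here are not relative to other genes. Over all tested probe sets the median was 0.01 in impaired and -0.04 in unimpaired rats against young.

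Whether chance can account for the counts was asked with 100 splits of the same arrays, the real one included. Chance alone is an unlikely account of the number of probe sets called against young rats. The counts were 78 in impaired rats against at most 3 in the other splits and 172 in unimpaired rats against at most 19. In all aged rats it was 168 against at most 4, each with 1 split as high. With 100 splits no share below 1 in 100 can be reached, and the splits do not tell which probe sets differ. Between the aged groups 0 probe sets were called, which all 100 splits must reach, so their count (1 at most) decides nothing. There 1 split, the real one, reached the 2199 probe sets at an unadjusted p below 0.05, with 2057 at most in the others. Chance cannot be excluded for the number of lists that passed: 61 splits had as many as the 6 in impaired rats (at most 14 in the others) and 21 as many as the 8 in unimpaired rats (at most 11). Likewise 95 had as many as the 1 between aged groups (at most 14) and 16 as many as the 11 in all aged rats (at most 15). Camera's preset correlation of 0.01 lies below the correlation estimated from the arrays for 28 of 29 lists, with 0.00251 for neuropeptides and trophic factors as the exception and 0.73 as the highest, so some lists can pass through genes that vary together; a structure among the samples was not tested.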
